A study of Homo sapiens with 18 samples.

How the data were processed

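Poly-A selected RNA of H1650 and PC9 cells was sequenced from TruSeq-compatible libraries, per the labels' protocols. The authors deposited 1 table of raw read counts per gene for each line, with 9 libraries in each, in which the counts are whole numbers and are not normalized. Per the submitters' processing notes, reads were handled with STAR on GRCh38 and analysed in R 4.0.1 with DESeq2 1.28.1. The version of STAR, the counting tool, the gene annotation release and whether strand was used in counting are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies (keratins 6A to 6C, HLA, HSPA1A and HSPA1B, SAA1 and SAA2, AKR1C, histone genes) can be split between them. The tables held 60603 and 60649 rows, and 60399 gene identifiers were in both, of which 52541 carried the same version, so that gene models can differ between the lines.

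Libraries were grouped by their labels into 3 groups of 3 per line. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates were compared before averaging: none of 18 pairs was identical, and the chi-square per degree of freedom ran from 1.523 to 5.94, above sampling noise in every pair. Replicate 1 of PC9 S100A9-inh stood apart, at 5.94 and 5.366 against replicates 2 and 3, which were at 1.998 with each other. Total counts ran from 17.40 to 27.11 M in H1650 and from 18.17 to 21.75 M in PC9, and genes with few counts have wide errors at that depth. Counting intervals and floors cover counting error only.

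Each line was fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, quasi-likelihood test over all 9 libraries), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common biological coefficient of variation was 0.0335 in H1650 and 0.0433 in PC9, which makes small differences pass. Standard errors (SE) are the absolute log2 fold change over the square root of F. For large changes that rest on few counts they can understate the error. Differences between lines were interaction contrasts in 1 edgeR model of all 18 libraries. Overlaps between lines were tested with Fisher's exact test, in which genes are not independent replicates. In total 46 gene lists (43 fixed by name and 3 by a name pattern) on pathways, lineages and markers of other cell types were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, with estimated correlations and fry as alternatives, for lists with at least 5 tested members (45 lists in H1650 and 42 in PC9). Gene symbols and positions came from GENCODE 29 and a table of gene names.

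The comparisons, the gene lists, the rule for named genes and the alternatives, except those named elsewhere as chosen after the results were seen, were chosen before the data were examined. The rule takes S100A9, S100A8, ALDH1A1, ALDH1A3 and EGFR, per comparison the 6 genes with the largest rise and fall among called genes at 5 CPM or more whose replicates do not overlap, up to 4 members per list with the smallest p, the genes with the largest shared change at 5 CPM or more in the higher group of each line, the 5 smallest interaction p values at 5 CPM or more in some group of each line and the leading genes of the reversal at 5 CPM or more in some group. Clone and locus names were left out, and genes below these levels can have larger fitted changes. The rule gives more genes than the text names, and which of them to print was chosen after their values were seen. A few of them are not reported here. Folds against a group with no count were taken against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has its 95% counting interval.

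The script was tested on simulated counts drawn from the libraries' means with 200 changed genes, up and down alike, taken from genes over 1 CPM. It recovered 64.2 to 88.1% of genes changed 1.5-fold, 76.1 to 98.5% of those changed 2-fold and 93.9 to 100% of those changed 4-fold, with 1.9 to 8.7% false calls. In the data 29.2 to 63.9% of tested genes were called within a line, a far larger share, so these rates need not hold there. Alternatives covered other scalings, filters, DESeq2 1.42.0, fold thresholds, fewer libraries, and leaving out each replicate in turn.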

Results

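RNA of H1650 and PC9, 2 human lung adenocarcinoma cell lines with an activating EGFR mutation, was measured by RNA sequencing in 3 groups per line, called BrM control, Tr-BrM control and Tr-BrM S100A9-inh in the labels. Each of the 6 groups held 3 libraries. The series concerns S100A9 in brain metastasis of EGFR-mutant lung cancer. What Tr stands for and how S100A9 was inhibited are not given in the sources used here, and the group names are therefore kept as labelled. Total counts per library were 17.40 to 27.11 M in H1650 and 18.17 to 21.75 M in PC9. In a principal component analysis of all tested genes, the first component held 78.6% of the variance in H1650 and placed the BrM libraries at -91.4 to -90.3, the Tr-BrM controls at 47.6 to 49.2 and the S100A9-inh libraries at 42.2 to 42.3. In PC9 it held 56.4% and placed the same groups at -52.5 to -51.5, 50.4 to 51.2 and 0.7 to 1.4. Levels are given as CPM (counts scaled to the library's TMM-adjusted total), mean ± SD with n = 3, and changes as log2 fold changes ± SE with n = 3 against 3. "Rose" and "fell" are used of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test.

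S100A9, the gene named as the target (ENSG00000163220, GRCh38 chromosome 1, 153357854 to 153361027, forward strand), encodes a calcium-binding protein that pairs with S100A8 to form calprotectin. In H1650 its level was 216.8, 206.3 and 198.9 CPM in the BrM controls, 336.2, 292.9 and 292.2 CPM in the Tr-BrM controls, and 95.19, 88.21 and 105.1 CPM under S100A9-inh. In PC9 it was 118.7, 126.6 and 119.7 CPM, then 738.8, 738.2 and 759.1 CPM, then 33.87, 30.43 and 35.45 CPM. S100A9 was thus higher in Tr-BrM than in BrM and lower under S100A9-inh than in either control group, in every library of both lines. S100A8 (ENSG00000143546, chromosome 1, 153390032 to 153391188, reverse strand) was also highest in the Tr-BrM controls of both lines, at 24.6 ± 0.795, 112 ± 9.96 and 43.9 ± 1.01 CPM in H1650 and 0.211 ± 0.15, 32.2 ± 1.48 and 1.02 ± 0.0532 CPM in PC9. ALDH1A1 (ENSG00000165092, chromosome 9, 72900662 to 73080442, reverse strand), which oxidises retinal to retinoic acid, was at 0.439 ± 0.132, 3.8 ± 0.111 and 2.52 ± 0.584 CPM in H1650 and 2.19 ± 0.0878, 111 ± 3.39 and 11.1 ± 0.416 CPM in PC9. ALDH1A3 (ENSG00000184254, chromosome 15, 100877714 to 100916626, forward strand) was at 56.8 ± 0.456, 11.6 ± 1.39 and 12.5 ± 0.826 CPM in H1650 and 88.4 ± 1.59, 88.1 ± 1.84 and 40.8 ± 3.19 CPM in PC9. EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628, forward strand) was at 471 ± 10.4, 365 ± 13.9 and 362 ± 5.39 CPM in H1650 and 975 ± 11.5, 1390 ± 19.5 and 918 ± 28.9 CPM in PC9.

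**Figure D1:**
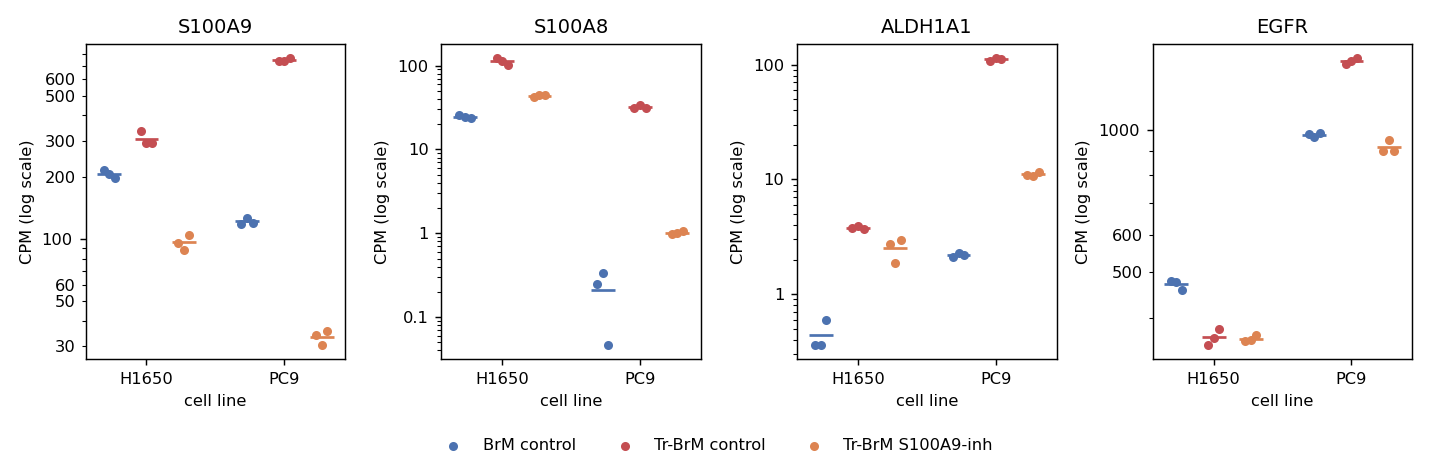
S100A9, S100A8, ALDH1A1 and EGFR in CPM (log scale) in the 3 libraries of each group (points) with the group mean (line), by cell line. S100A9 in PC9 rose from a mean of 122 CPM in BrM to 745 CPM in Tr-BrM controls and was at 33.2 CPM under S100A9-inh, while in H1650 the means were 207, 307 and 96.2 CPM.

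In H1650, S100A9 rose by 0.56 ± 0.0489 on the log2 scale in Tr-BrM controls against BrM controls (adjusted p = 3.91e-11), S100A8 by 2.19 ± 0.0565 and ALDH1A1 by 3.14 ± 0.257, while the related ALDH1A3 changed by -2.28 ± 0.0691 and EGFR by -0.37 ± 0.0316. The placental hormone gene INSL4, the fibrocystin gene PKHD1 and the epithelial transcription factor ELF5 had no count in any BrM library and were at least 125-fold, at least 136-fold and at least 115-fold higher in Tr-BrM, against a floor of 3 counts over the group. The folate receptor FOLR1, with 1 count in BrM, was 322-fold higher with a counting interval from 57.4 to 12700, and PIP5K1B, also with 1 count, 428-fold higher with an interval from 76.5 to 16900. ANKFN1 was 349-fold higher from 3 counts, with an interval from 119 to 1690, and the serine protease inhibitor SERPINB13 rose by 8.45 ± 0.223. The lymphangiogenic factor VEGFC fell by 6.54 ± 0.3, CASP14, a caspase of keratinocyte differentiation, changed by -6.12 ± 0.17, MSLNL by -6.54 ± 0.342, FAXDC2 by -5.92 ± 0.107 and the phospholipase PLCB4 by -5.87 ± 0.263. NWD1 had 3 counts in Tr-BrM and was 115-fold lower there, with an interval from 39 to 561. The hyaluronan receptor CD44 changed by -5.54 ± 0.0567, the lysyl oxidase LOXL2 by -5.44 ± 0.0577 and the receptor tyrosine kinase AXL by -2.56 ± 0.0408.

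Among the gene lists fixed beforehand, the type I interferon response was lower in H1650 Tr-BrM than in BrM: 6 of 44 rose, 37 fell and 1 did not pass (6 and 37 adjusted over the list alone); camera adjusted p was 3.13e-08, and adjusted p = 0.158 with an estimated correlation. OASL changed by -2.79 ± 0.0457, IFIT3 by -2.25 ± 0.04, IFIT2 by -2.12 ± 0.0391 and RIGI, a cytosolic RNA sensor, by -1.56 ± 0.0409. Of antigen presentation by MHC class I, 2 of 19 rose, 14 fell and 3 did not pass (2 and 14 adjusted over the list alone). ERAP2 at -1.36 ± 0.0591 and the peptide transporter TAP1 at -0.66 ± 0.0409 were among the members, and the camera adjusted p was 0.00166, and adjusted p = 0.155 with an estimated correlation. Of hypoxia and glycolysis genes, 4 of 35 rose, 29 fell and 2 did not pass (4 and 29 adjusted over the list alone); camera adjusted p was 1.1e-06, and adjusted p = 0.147 with an estimated correlation. PFKP, PKM and the glucose transporter SLC2A1 changed by -1.68 ± 0.0351, -1.17 ± 0.0288 and -1.29 ± 0.0313, while SLC2A3 rose by 1.86 ± 0.0405. Of cholesterol biosynthesis genes, 20 of 24 rose, 1 fell and 3 did not pass (20 and 1 adjusted over the list alone). The mevalonate kinase MVK at 1.58 ± 0.0487 and STARD4 at 1.66 ± 0.0745 were among the members, and the camera adjusted p was 5.1e-06, and adjusted p = 0.0623 with an estimated correlation. Of fatty acid synthesis and desaturation genes, 14 of 24 rose, 5 fell and 5 did not pass (14 and 5 adjusted over the list alone). FABP5 at 2.10 ± 0.062 and the desaturase SCD at 1.33 ± 0.0293 were among the members, and the camera adjusted p was 0.0295, and adjusted p = 0.156 with an estimated correlation.

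Cell cycle lists moved apart in H1650 Tr-BrM. Of G2/M genes, 33 of 40 rose, 4 fell and 3 did not pass (33 and 4 adjusted over the list alone). The mitotic kinase AURKA at 1.15 ± 0.0319 and TOP2A at 0.78 ± 0.0321 were among the members, and the camera adjusted p was 2.04e-06, and adjusted p = 0.158 with an estimated correlation. Of DNA replication genes, 4 of 46 rose, 35 fell and 7 did not pass (4 and 35 adjusted over the list alone). MCM10 at -1.17 ± 0.0495, MCM3 at -0.51 ± 0.0331 and RRM2 at -0.45 ± 0.0315 were among the members, and the camera adjusted p was 2.43e-05, and adjusted p = 0.158 with an estimated correlation. Of histone genes taken by a name pattern, which also takes some replication-independent ones, 4 of 45 rose, 29 fell and 12 did not pass (4 and 31 adjusted over the list alone); camera adjusted p was 0.000331, and adjusted p = 0.0903 with an estimated correlation. Their copies are near-identical and mostly lack poly-A tails, so their counts are uncertain. Of p53 targets, 15 of 22 rose, 3 fell and 4 did not pass (15 and 3 adjusted over the list alone). BTG2 at 1.57 ± 0.0948, MDM2 at 0.92 ± 0.0591 and CDKN1A at 0.49 ± 0.0309 were among the members, and the camera adjusted p was 0.0148, and adjusted p = 0.155 with an estimated correlation. Of heat shock genes, 1 of 16 rose, 13 fell and 2 did not pass (1 and 13 adjusted over the list alone). HSPB1 at -0.86 ± 0.0488 was among the members, and the camera adjusted p was 0.019, and adjusted p = 0.158 with an estimated correlation.

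Squamous and epithelial lists had medians above 0 in H1650 Tr-BrM. Of squamous and basal lineage genes, 15 of 25 rose, 5 fell and 5 did not pass (16 and 5 adjusted over the list alone). The keratin KRT17 at 4.26 ± 0.0363, the cornified envelope gene SPRR3 at 6.16 ± 0.0721 and TRIM29 at 1.93 ± 0.0337 were among the members, and the camera adjusted p was 0.00251, and adjusted p = 0.174 with an estimated correlation. KRT6A, which shares reads with KRT6B and KRT6C, was at 2.11 ± 0.0365. Of epithelial genes, 21 of 34 rose, 9 fell and 4 did not pass (22 and 9 adjusted over the list alone). GRHL3 at 2.73 ± 0.0795 and CLDN1 at 1.52 ± 0.0372 were among the members, and the camera adjusted p was 0.019, and adjusted p = 0.155 with an estimated correlation. P-cadherin CDH3 changed by -3.04 ± 0.0372. Of mesenchymal genes, 15 of 35 rose, 16 fell and 4 did not pass (16 and 16 adjusted over the list alone); camera adjusted p was 0.737, and adjusted p = 0.815 with an estimated correlation. Members moved both ways: SPARC changed by -3.05 ± 0.0437, tenascin TNC by -2.30 ± 0.0328 and fibronectin FN1 rose by 1.84 ± 0.0289. Markers of other cell types moved with these groups in H1650. Of astrocyte markers, 10 of 12 rose, 1 fell and 1 did not pass (10 and 1 adjusted over the list alone); camera adjusted p was 0.00166, and adjusted p = 0.147 with an estimated correlation, and GFAP was at 8.68, 63.2 and 31.7 CPM in BrM, Tr-BrM and S100A9-inh. Of microglia and myeloid markers, 14 of 17 rose, 1 fell and 2 did not pass (14 and 1 adjusted over the list alone); camera adjusted p was 0.00232, and adjusted p = 0.267 with an estimated correlation, and the leukocyte gene PTPRC was at 1.33, 6.25 and 4.39 CPM.

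Of 17937 genes tested in H1650, 5777 were higher and 5692 lower in Tr-BrM than in BrM, of which 2311 and 1379 by at least 1 on the log2 scale, and scaling by library size alone gave 6802 higher and 4672 lower. Replicates did not overlap between the groups for 67.5% of genes, where chance gives 10%. All 14 lists past the camera threshold lost it with an estimated correlation.

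In PC9, S100A9 rose by 2.62 ± 0.0424 in Tr-BrM controls against BrM controls (adjusted p = 1.64e-29), S100A8 by 7.23 ± 0.189, ALDH1A1 by 5.66 ± 0.0843 and EGFR by 0.52 ± 0.032, while ALDH1A3 was at -0.01 ± 0.0508 (adjusted p = 0.925). S100A8 had only 1 to 7 counts per BrM library, so its SE is likely too small. The carboxylesterase CES1 rose by 11.996 ± 0.0856, the keratin KRT23 by 10.40 ± 0.127 and the basal keratin KRT5 by 7.44 ± 0.192. SLC34A2, a phosphate transporter of alveolar type II cells, and fibromodulin FMOD had no count in BrM and were at least 256-fold and at least 121-fold higher in Tr-BrM. The amino acid transporter SLC6A14, with 3 counts in BrM, was 2040-fold higher with an interval from 699 to 9910, and GGT6, with 1 count, 651-fold higher with an interval from 116 to 25800. N-cadherin, CDH2, and the transcription factor TSHZ3 had no count in Tr-BrM and were at least 793-fold and at least 107-fold lower there. The membrane skeleton gene EPB41L2 changed by -8.72 ± 0.108, CDYL2 by -8.04 ± 0.193, L-plastin LCP1 by -7.02 ± 0.106, the aminotransferase BCAT1 by -6.71 ± 0.122, AXL by -1.83 ± 0.0856 and TLR4, a receptor for S100A8 and S100A9, by -6.18 ± 0.207.

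Of cholesterol biosynthesis genes in PC9, 2 of 25 rose, 22 fell and 1 did not pass (2 and 22 adjusted over the list alone). INSIG1 at -2.29 ± 0.0596, MVK at -2.02 ± 0.0777 and LSS at -1.61 ± 0.0527 were among the members, and the camera adjusted p was 4.8e-08, and adjusted p = 0.018 with an estimated correlation. Of DNA replication genes, 36 of 46 rose, 2 fell and 8 did not pass (36 and 2 adjusted over the list alone). CDC45 at 1.11 ± 0.0538 and CDC6 at 0.88 ± 0.0429 were among the members, and the camera adjusted p was 3.97e-07, and adjusted p = 0.018 with an estimated correlation. Of G2/M genes, 32 of 39 rose, 2 fell and 5 did not pass (32 and 2 adjusted over the list alone). ANLN at 0.88 ± 0.0422 and CDC20 at 0.74 ± 0.0404 were among the members, and the camera adjusted p was 3.97e-07, and adjusted p = 0.218 with an estimated correlation. Of mesenchymal genes, 2 of 22 rose, 13 fell and 7 did not pass (2 and 14 adjusted over the list alone). FN1 at -4.74 ± 0.0377, TNC at -3.20 ± 0.0682 and LOXL2 at -1.91 ± 0.0608 were among the members, and the camera adjusted p was 0.000609, and adjusted p = 0.131 with an estimated correlation. Of TGF-beta response genes, 2 of 20 rose, 14 fell and 4 did not pass (2 and 14 adjusted over the list alone). LTBP2 at -1.58 ± 0.0412, PMEPA1 at -1.56 ± 0.034 and TGFBI at -1.40 ± 0.0392 were among the members, and the camera adjusted p was 0.00391, and adjusted p = 0.195 with an estimated correlation. Of NF-kappaB targets and inflammatory cytokines, 19 of 29 rose, 5 fell and 5 did not pass (20 and 5 adjusted over the list alone). Lipocalin LCN2 at 2.11 ± 0.0457 and TNFAIP3 at 2.02 ± 0.0779 were among the members, and the camera adjusted p was 0.00161, and adjusted p = 0.0836 with an estimated correlation. The prostaglandin synthase PTGS2 changed by -4.06 ± 0.162. SAA1, which shares reads with SAA2, was at 6.76 ± 0.207. Of heat shock genes, 14 of 18 rose, 3 fell and 1 did not pass (15 and 3 adjusted over the list alone). HSP90AA1 at 0.84 ± 0.0336 was among the members, and the camera adjusted p was 0.0041, and adjusted p = 0.109 with an estimated correlation. Of squamous and basal lineage genes, 10 of 15 rose, 4 fell and 1 did not pass (11 and 4 adjusted over the list alone). KRT17 at 6.93 ± 0.172 was among the members, and the camera adjusted p was 0.00973, and adjusted p = 0.218 with an estimated correlation.

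Of 16169 genes tested in PC9, 4784 were higher and 4900 lower in Tr-BrM than in BrM, of which 956 and 1097 by at least 1 on the log2 scale, and replicates did not overlap for 65.7%. Which direction held more genes depended on scaling, with 5106 higher and 4617 lower by the upper quartile. Of the 8 lists past the camera threshold, 2 kept it with an estimated correlation, and leaving out BrM control replicate 2 gave 13 lists. Of astrocyte markers, 3 of 5 rose, 0 fell and 2 did not pass (3 and 0 adjusted over the list alone); camera adjusted p was 0.0527, and adjusted p = 0.195 with an estimated correlation.

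**Figure D2:**
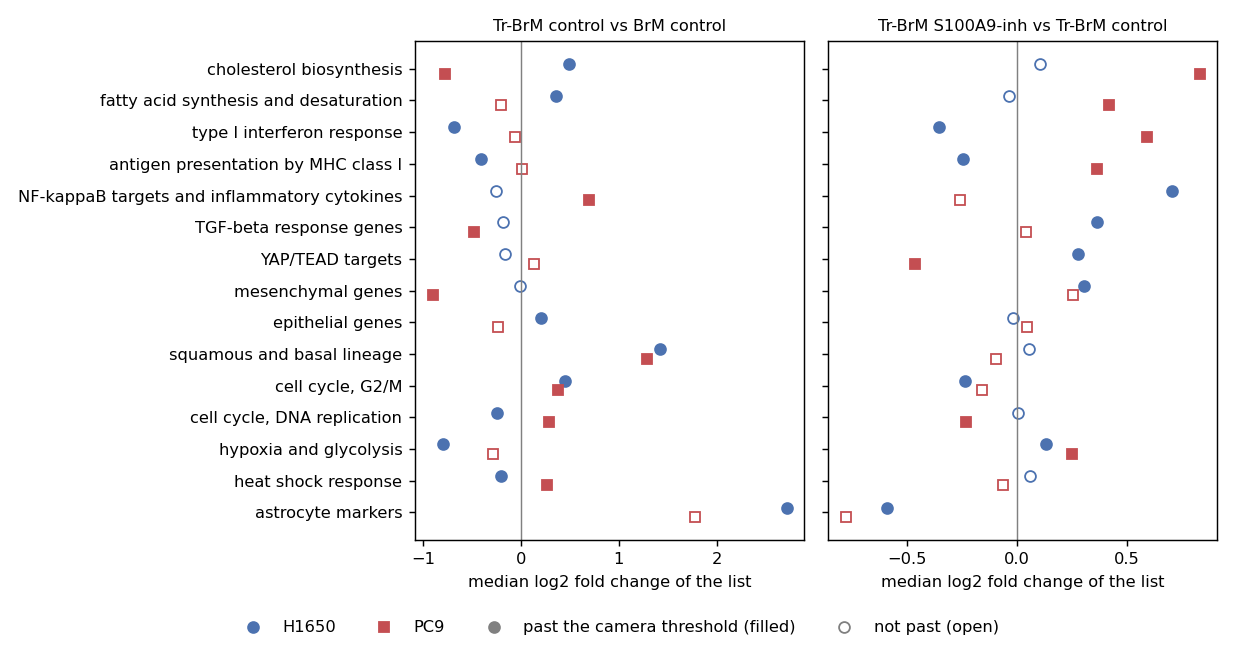
Median log2 fold change (x axis) of 15 of the gene lists fixed beforehand, in Tr-BrM against BrM controls (left) and in S100A9-inh against Tr-BrM controls (right), for H1650 (circles) and PC9 (squares), filled where the list passed the camera threshold. Cholesterol biosynthesis sits at 0.49 in H1650 and -0.78 in PC9 on the left, and the type I interferon response at -0.35 in H1650 and 0.59 in PC9 on the right.

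The Tr-BrM against BrM changes of both lines were compared over the 14888 genes tested in both. Among genes at 5 CPM or more in the higher group of each line, ordered by the smaller of the 2 fitted changes, those that rose in both began with GGT6 (6.33 ± 0.184 in H1650), the keratins KRT17 and KRT13, the latter at 3.78 ± 0.176 in H1650 and 4.68 ± 0.273 in PC9, PIP5K1B (3.62 ± 0.228 in PC9), the adaptor EFS (3.26 ± 0.119 and 3.57 ± 0.219) and the lipid transporter ABCA12 (3.17 ± 0.0636 and 3.01 ± 0.106). Lower in both, in the same order, were CDYL2 (-5.17 ± 0.189 in H1650), the nuclear receptor NR2F1 (-4.11 ± 0.142 and -3.70 ± 0.242), TSHZ3 (-3.09 ± 0.139 in H1650), EPB41L2 (-2.75 ± 0.0619 in H1650), TNC and the proteoglycan SRGN (-2.29 ± 0.07 and -2.55 ± 0.0893). Over all called genes, 1353 rose in both, where independent lists give 1370.7 (two-sided Fisher's exact p = 0.497), and 1680 fell in both, where they give 1631.7 (p = 0.0753). Genes that rose in H1650 and fell in PC9 numbered 1702 against 1422.3 by chance, and the reverse 1787 against 1572.5. The same-direction total was 1.01 times that of independent lists, 0.95 times with a stricter filter and 1.26 times with DESeq2 over the 19800 genes it tested in both lines. With DESeq2 on the genes edgeR tested in both, a check chosen after the result was seen, it was 1.06 times, with 1134 risen in both against 1104.7 (two-sided Fisher's exact p = 0.23) and 1385 fallen against 1267.8 (p = 3.74e-06), so whether the overlap exceeded chance depended on the test and the genes taken. With an absolute log2 fold change of at least 1, where the split by direction was chosen after the result was seen, 206 genes rose in both against 61.1 by chance and 133 fell in both against 65.9, while 177 and 132 moved in opposite directions against 76.1 and 52.9. Since same and opposite directions both exceeded chance, this excess does not show a shared direction of change. Over the 14888 genes, the log2 fold changes of the lines correlated by 0.039 (Pearson) and -0.03 (Spearman).

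The difference between the lines was tested as an interaction, coded as PC9 minus H1650. It passed for 10422 of 19076 genes. FN1 differed by -6.58 ± 0.0498, the surface glycoprotein mesothelin, MSLN, by 8.64 ± 0.0919, CD44 by 6.18 ± 0.066, moesin, MSN, by 4.05 ± 0.0498 and the endothelial lipase LIPG by -6.18 ± 0.0813. MSLN was at -4.85 ± 0.0635 in H1650 and 3.80 ± 0.0639 in PC9, CD44 was at 0.64 ± 0.0294 in PC9, MSN at -3.02 ± 0.037 and 1.03 ± 0.0307, and LIPG at 4.20 ± 0.0692 and -1.99 ± 0.0437. Cholesterol biosynthesis genes moved in opposite directions (median difference -1.44, camera adjusted p = 1.89e-11 and adjusted p = 0.000156 with an estimated correlation), as did DNA replication genes (median difference 0.59, camera adjusted p = 5.69e-10 and adjusted p = 0.00283 with an estimated correlation) and heat shock genes (median difference 0.67, camera adjusted p = 0.000871 and adjusted p = 0.019 with an estimated correlation).

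Under S100A9-inh, S100A9 fell by 1.67 ± 0.0512 in H1650 against Tr-BrM controls (adjusted p = 1.47e-19), S100A8 changed by -1.36 ± 0.0503, ALDH1A1 by -0.58 ± 0.175 (adjusted p = 0.0117), while ALDH1A3 was at 0.11 ± 0.0816 (adjusted p = 0.368) and EGFR at -0.01 ± 0.0316 (adjusted p = 0.864). The call for ALDH1A1 was lost without S100A9-inh replicate 2 (-0.42, adjusted p = 0.0765) and with DESeq2, over alternatives ranging from adjusted p = 0.00748 to 0.0768. The cytokine IL32 rose by 1.94 ± 0.117, the EGFR ligand EGF by 1.82 ± 0.0977, the Wnt modulator DACT1 by 1.77 ± 0.123, the protease inhibitor SPINK6 by 1.65 ± 0.0556, the actin-binding NEXN by 1.61 ± 0.105 and the melanin-pathway gene TYRP1 by 3.12 ± 0.469. AGAP2 changed by -2.31 ± 0.238, the inducible chaperone HSPA6, which resembles HSPA1A, by -1.89 ± 0.142, FOLR1 by -1.74 ± 0.173, the epidermal transcription factor ZNF750 by -1.67 ± 0.167 and CYP2W1 by -1.63 ± 0.136.

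Of type I interferon response genes, 0 of 44 rose, 37 fell and 7 did not pass (0 and 37 adjusted over the list alone). OAS1 at -0.77 ± 0.0379, MX1 at -0.67 ± 0.0296 and IFI6 at -0.58 ± 0.0278 were among the members, and the camera adjusted p was 1.62e-19, and adjusted p = 0.0778 with an estimated correlation. Of antigen presentation by MHC class I, 2 of 19 rose, 12 fell and 5 did not pass (2 and 14 adjusted over the list alone). NLRC5, the class I transactivator, at -0.57 ± 0.076 was among the members, and the camera adjusted p was 0.000287, and adjusted p = 0.0797 with an estimated correlation. HLA-B and HLA-C, which are polymorphic and share reads, were at -0.48 ± 0.0436 and -0.45 ± 0.03. Of G2/M genes, 0 of 40 rose, 29 fell and 11 did not pass (0 and 29 adjusted over the list alone). AURKA at -0.48 ± 0.0307 and PLK1 at -0.40 ± 0.0315 were among the members, and the camera adjusted p was 8.62e-12, and adjusted p = 0.0778 with an estimated correlation. Of NF-kappaB targets and inflammatory cytokines, 24 of 33 rose, 1 fell and 8 did not pass (25 and 1 adjusted over the list alone). RELB at 1.29 ± 0.0576, BIRC3 at 1.03 ± 0.0586, NFKB2 at 0.75 ± 0.0331 and IL6 at 1.12 ± 0.0675 were among the members, and the camera adjusted p was 2.17e-10, and adjusted p = 0.0797 with an estimated correlation. Of YAP/TEAD targets, 18 of 22 rose, 0 fell and 4 did not pass (19 and 0 adjusted over the list alone). ANKRD1 at 1.33 ± 0.053, CCN1 at 1.32 ± 0.0291 and CCN2 at 1.32 ± 0.066 were among the members, and the camera adjusted p was 1.2e-10, and adjusted p = 0.0778 with an estimated correlation. Of TGF-beta response genes, 15 of 20 rose, 2 fell and 3 did not pass (15 and 2 adjusted over the list alone). TGFB2 at 1.13 ± 0.0695 and PMEPA1 at 0.87 ± 0.0312 were among the members, and the camera adjusted p was 1.58e-07, and adjusted p = 0.0778 with an estimated correlation. Of mesenchymal genes, 15 of 35 rose, 2 fell and 18 did not pass (16 and 3 adjusted over the list alone). TNC at 1.285 ± 0.0329 and AXL at 0.90 ± 0.0437 were among the members, and the camera adjusted p was 0.000484, and adjusted p = 0.0778 with an estimated correlation.

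Of integrins and laminins, 12 of 28 rose, 5 fell and 11 did not pass (12 and 6 adjusted over the list alone). ITGB6 at 1.39 ± 0.0786 and LAMA3 at 0.78 ± 0.0298 were among the members, and the camera adjusted p was 0.00317, and adjusted p = 0.0778 with an estimated correlation. Of MAPK output genes, 8 of 20 rose, 1 fell and 11 did not pass (8 and 1 adjusted over the list alone). FOSL1 at 1.16 ± 0.0959 was among the members, and the camera adjusted p was 0.00469, and adjusted p = 0.152 with an estimated correlation. Of matrix proteases and their inhibitors, 12 of 30 rose, 5 fell and 13 did not pass (14 and 5 adjusted over the list alone). ADAMTS1 at 1.05 ± 0.051 and the urokinase receptor PLAUR at 1.01 ± 0.0502 were among the members, and the camera adjusted p was 0.00469, and adjusted p = 0.304 with an estimated correlation. Of hypoxia and glycolysis genes, 16 of 35 rose, 5 fell and 14 did not pass (17 and 7 adjusted over the list alone). EGLN3 at 0.95 ± 0.0655 and BNIP3 at 0.68 ± 0.0429 were among the members, and the camera adjusted p was 0.00162, and adjusted p = 0.192 with an estimated correlation. Of aldehyde dehydrogenases, 1 of 18 rose, 10 fell and 7 did not pass (1 and 11 adjusted over the list alone). ALDH3B1 at -0.66 ± 0.0541 and ALDH2 at -0.53 ± 0.0661 were among the members, and the camera adjusted p was 0.0037, and adjusted p = 0.0778 with an estimated correlation. ALDH1B1 rose by 0.94 ± 0.0549. Of the S100 family, which holds S100A9 itself, 1 of 17 rose, 10 fell and 6 did not pass (2 and 10 adjusted over the list alone). S100P at -1.96 ± 0.229 was among the members, and the camera adjusted p was 0.0128, and adjusted p = 0.211 with an estimated correlation. Of retinoid receptors and cofactors, 0 of 12 rose, 6 fell and 6 did not pass (2 and 8 adjusted over the list alone). RXRA at -0.43 ± 0.0325 was among the members, and the camera adjusted p was 0.0104, and adjusted p = 0.32 with an estimated correlation. Of receptors and ligands that bypass EGFR, 9 of 23 rose, 5 fell and 9 did not pass (9 and 5 adjusted over the list alone); camera adjusted p was 0.0409, and adjusted p = 0.339 with an estimated correlation. Of astrocyte markers, measured beside these groups, 1 of 12 rose, 6 fell and 5 did not pass (1 and 6 adjusted over the list alone). FGFR3 at -0.89 ± 0.0799 and GFAP at -0.99 ± 0.153 were among the members, and the camera adjusted p was 0.0172, and adjusted p = 0.151 with an estimated correlation. Of microglia and myeloid markers, 2 of 17 rose, 8 fell and 7 did not pass (3 and 9 adjusted over the list alone). FCGR3A at -1.84 ± 0.219 was among the members, and the camera adjusted p was 0.0588, and adjusted p = 0.478 with an estimated correlation.

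Of the 17937 genes tested, 2762 were higher and 2468 lower under S100A9-inh, of which 199 and 167 by at least 1 on the log2 scale, and scaling by library size alone gave 2201 higher and 3193 lower. All 16 lists past the camera threshold lost it with an estimated correlation. The calls for GFAP (adjusted p = 0.12 with DESeq2, 9.33e-70 to 0.12 over the alternatives) and TYRP1 (adjusted p = 0.0509 with robust empirical Bayes, 3.88e-85 to 0.0509) were each lost under at least 1 alternative. The log2 fold change of TYRP1 ran from 2.644 to 4.775 over the alternatives.

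In PC9, S100A9 fell by 4.49 ± 0.0487 under S100A9-inh against Tr-BrM controls (adjusted p = 1.14e-33), S100A8 changed by -4.98 ± 0.144, ALDH1A1 by -3.32 ± 0.0648, ALDH1A3 by -1.11 ± 0.0545 and EGFR by -0.60 ± 0.032. EPB41L2 rose by 7.59 ± 0.119, CDYL2 by 6.39 ± 0.241, TLR4 by 4.44 ± 0.256, dystrophin DMD by 4.35 ± 0.276, CALML5 by 4.25 ± 0.217 and the interferon-inducible tetherin BST2 by 3.79 ± 0.105. SLC34A2 changed by -6.32 ± 0.258, KRT5 by -5.74 ± 0.158, KRT4 by -4.46 ± 0.119, FMOD by -4.12 ± 0.28 and KRT17 by -3.61 ± 0.115. CDH2, with no count in Tr-BrM controls, was at least 69.4-fold higher under S100A9-inh.

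Of cholesterol biosynthesis genes, 22 of 25 rose, 0 fell and 3 did not pass (22 and 0 adjusted over the list alone). INSIG1 at 1.92 ± 0.0605 and FDFT1 at 0.92 ± 0.0369 were among the members, and the camera adjusted p was 8.58e-11, and adjusted p = 0.0166 with an estimated correlation. Of fatty acid synthesis and desaturation genes, 16 of 24 rose, 5 fell and 3 did not pass (16 and 5 adjusted over the list alone). LPIN1 at 1.58 ± 0.0502, SCD at 1.10 ± 0.0316 and FASN at 0.98 ± 0.0395 were among the members, and the camera adjusted p was 0.00113, and adjusted p = 0.0817 with an estimated correlation. Of type I interferon response genes, 23 of 35 rose, 4 fell and 8 did not pass (23 and 4 adjusted over the list alone). PARP9 at 0.82 ± 0.0763 and OAS3 at 0.75 ± 0.0551 were among the members, and the camera adjusted p was 0.000508, and adjusted p = 0.0817 with an estimated correlation. Of antigen presentation by MHC class I, 16 of 20 rose, 2 fell and 2 did not pass (16 and 3 adjusted over the list alone). NLRC5 at 1.09 ± 0.0681 and ERAP2 at 1.06 ± 0.0674 were among the members, and the camera adjusted p was 0.000542, and adjusted p = 0.0817 with an estimated correlation. Of DNA replication genes, 5 of 46 rose, 31 fell and 10 did not pass (5 and 31 adjusted over the list alone). PCNA at -0.59 ± 0.0358 and CDC6 at -0.64 ± 0.0425 were among the members, and the camera adjusted p was 0.00014, and adjusted p = 0.0378 with an estimated correlation. Of YAP/TEAD targets, 4 of 21 rose, 15 fell and 2 did not pass (4 and 15 adjusted over the list alone). ANKRD1 at -1.47 ± 0.097 and tissue factor F3 at -1.30 ± 0.0401 were among the members, and the camera adjusted p was 0.00186, and adjusted p = 0.0817 with an estimated correlation. Of hypoxia and glycolysis genes, 23 of 35 rose, 3 fell and 9 did not pass (23 and 3 adjusted over the list alone). NDRG1 at 1.83 ± 0.0516 and LDHA at 0.57 ± 0.0286 were among the members, and the camera adjusted p was 0.000508, and adjusted p = 0.331 with an estimated correlation.

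Of mitochondrially encoded protein genes, 0 of 13 rose, 13 fell and 0 did not pass (0 and 13 adjusted over the list alone). MT-CO3 at -0.50 ± 0.0293 and MT-ATP6, whose transcript overlaps a neighbour, at -0.55 ± 0.0319 were among the members, and the camera adjusted p was 0.00014, and adjusted p = 0.0817 with an estimated correlation. Of ribosomal protein genes, which have many processed pseudogenes, 54 of 80 rose, 12 fell and 14 did not pass (55 and 12 adjusted over the list alone). RPL13A at 0.68 ± 0.0308 was among the members, and the camera adjusted p was 0.000508, and adjusted p = 0.465 with an estimated correlation. Of apoptosis regulators, 15 of 25 rose, 4 fell and 6 did not pass (15 and 4 adjusted over the list alone). BMF at 1.27 ± 0.121 and BCL2L2 at 0.65 ± 0.0659 were among the members, and the camera adjusted p was 0.0284, and adjusted p = 0.121 with an estimated correlation. Of retinoid receptors and cofactors, 7 of 12 rose, 1 fell and 4 did not pass (7 and 1 adjusted over the list alone). RARG at 0.87 ± 0.0484 and RXRA at 0.58 ± 0.0404 were among the members, and the camera adjusted p was 0.0196, and adjusted p = 0.121 with an estimated correlation. Of stem-like and Notch/Wnt genes, 5 of 23 rose, 12 fell and 6 did not pass (5 and 12 adjusted over the list alone). CD24 at -1.16 ± 0.0436 and CD44 at -0.81 ± 0.0295 were among the members, and the camera adjusted p was 0.0284, and adjusted p = 0.201 with an estimated correlation. Of aldehyde dehydrogenases, 2 of 18 rose, 9 fell and 7 did not pass (2 and 9 adjusted over the list alone); camera adjusted p was 0.0396, and adjusted p = 0.331 with an estimated correlation. Of neuronal and synaptic genes, 0 of 11 rose, 5 fell and 6 did not pass (0 and 5 adjusted over the list alone). UCHL1 at -1.05 ± 0.0357 was among the members, and the camera adjusted p was 0.0396, and adjusted p = 0.161 with an estimated correlation. Of histone genes, 15 of 29 rose, 3 fell and 11 did not pass (16 and 3 adjusted over the list alone); camera adjusted p was 0.0284, and adjusted p = 0.121 with an estimated correlation. Of mesenchymal genes, 10 of 22 rose, 5 fell and 7 did not pass (10 and 5 adjusted over the list alone). TNC at 2.44 ± 0.0701 and AXL at 1.60 ± 0.0872 were among the members, and the camera adjusted p was 0.121, and adjusted p = 0.331 with an estimated correlation. FN1 changed by -0.97 ± 0.0343.

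Of the 16169 genes tested in PC9, 4260 were higher and 4227 lower under S100A9-inh, of which 796 and 467 by at least 1 on the log2 scale, while RLE scaling gave 4210 higher and 4283 lower, DESeq2 3626 and 3737, upper-quartile scaling 4512 and 3974 and library size alone 4625 and 3861. S100A9-inh replicate 1 lay further from its 2 partners than these from each other, and without it 8397 genes passed. Of the 15 lists past the camera threshold, 2 kept it with an estimated correlation, namely cholesterol biosynthesis and DNA replication. The fixed lists of retinoic acid induced genes and of retinoid metabolism and transport did not pass it in either line, for Tr-BrM or for S100A9-inh. The same held for S100A9 receptors and partners and for genes described in brain metastasis.

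Genes that changed the same way under S100A9-inh in both lines included the kinase NUAK1 (0.95 ± 0.0574 in H1650 and 1.02 ± 0.129 in PC9), LOXL2 (0.90 ± 0.0906 and 1.37 ± 0.0622), the cytokine IL11 (1.07 ± 0.156 and 0.87 ± 0.071), WNT5B (0.83 ± 0.15 and 1.19 ± 0.0993), TNC and AXL, which rose. The glycine decarboxylase GLDC (-1.21 ± 0.0757 and -1.49 ± 0.0815), KRT13 (-1.14 ± 0.119 and -1.67 ± 0.186), osteopontin SPP1 (-1.12 ± 0.116 and -2.23 ± 0.0477) and WNT6 (-1.07 ± 0.0716 and -2.29 ± 0.086) fell with S100A9 and S100A8. Over all called genes, 658 rose in both lines against 678.5 by chance (two-sided Fisher's exact p = 0.324) and 494 fell in both against 594.3 (p = 1.26e-07), while 1027 rose in H1650 and fell in PC9 against 674.1 and 905 did the reverse against 598.1. The same-direction total was 0.91 times that of independent lists, 0.79 times with a stricter filter and 1.01 times with DESeq2, where 478 rose in both against 425 (two-sided Fisher's exact p = 0.00233) and 356 fell in both against 398.3 (p = 0.0103). On the genes edgeR tested in both, DESeq2 gave 477 against 445.2 (two-sided Fisher's exact p = 0.0679) and 356 against 417.6 (p = 0.000209). At an absolute log2 fold change of at least 1, again split by direction after the result was seen, 12 genes rose in both against 4.1 by chance and 13 fell in both against 1.6, while 12 and 17 moved in opposite directions against 2.2 and 3.1. Same and opposite directions again both exceeded chance. Over all genes tested in both lines, the log2 fold changes correlated by -0.072 (Pearson) and -0.123 (Spearman). The interaction passed for 7704 of 19076 genes. KRT17 differed by -4.52 ± 0.0907, with 0.91 ± 0.0298 in H1650, EPB41L2 by 7.16 ± 0.165, BST2 by 4.09 ± 0.0961, thrombospondin THBS1 by -1.96 ± 0.0485 and the kallikrein KLK5 by -2.41 ± 0.0599. Cholesterol biosynthesis genes had the smallest list p, with a median difference of 0.713 (camera adjusted p = 1.08e-10 and adjusted p = 0.00022 with an estimated correlation). Type I interferon genes, lower in H1650 and higher in PC9, differed by a median of 0.996, camera adjusted p = 5.13e-10 and adjusted p = 0.00064 with an estimated correlation, and YAP/TEAD targets by -0.67, camera adjusted p = 3.79e-07 and adjusted p = 0.023 with an estimated correlation. MHC class I, DNA replication and fatty acid synthesis lists also kept the camera threshold with an estimated correlation (adjusted p = 0.0249 each). Other splits of the libraries gave up to 17 lists past the threshold, against 15 in the real one, so chance is not excluded for that count.

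How far S100A9-inh cells stood from BrM was measured in both lines. In H1650, 1444 genes rose in Tr-BrM and fell under S100A9-inh (25% of those that rose, 794.9 by chance) and 1485 fell and then rose (26.1%, 876.5 by chance), with AGAP2, HSPA6, FOLR1, ZNF750 and CYP2W1 leading, among genes at 5 CPM or more in some group, the first group and PLCB4 (2.51 ± 0.404 under S100A9-inh), VSTM1 (2.40 ± 0.554), BNC1 (1.97 ± 0.245), MARCHF4 (1.82 ± 0.213) and EGF the second. In PC9, 2886 rose and then fell (60.3%, 1250.7 by chance) and 2982 fell and then rose (60.9%, 1291 by chance), led, at the same minimum level, by SLC34A2, KRT5, S100A8, KRT4 and FMOD, and by CDH2, EPB41L2, CDYL2, TLR4 and DMD. Other genes moved further from BrM. In H1650, 695 rose in both contrasts (889.6 by chance) and 535 fell in both (783.2 by chance). For PC9 these were 292 (1260.4 by chance) and 359 (1281 by chance). S100A9-inh cells still differed from BrM for 11416 genes in H1650 (5827 higher, 5589 lower, against 6421 and 4921 with scaling by library size alone) and 7489 in PC9 (3675 higher, 3814 lower, against 4387 and 3182 with upper-quartile scaling). Both contrasts share the Tr-BrM controls with opposite sign, and unchanged groups simulated against those controls gave a correlation of -0.504 in H1650 and -0.509 in PC9 across genes, beside -0.285 and -0.67 observed. The covariance was -0.1382 in H1650 and -0.4187 in PC9, against a simulated -0.018 in each, a difference of -0.1202 and -0.4007. In 20 such simulated sets per line, at most 1 gene in H1650 and 0 in PC9 were called in opposite directions, but these sets held no changed gene. The 3 shared controls were not divided between the contrasts, and part of the excess over chance in the counts may come from them.

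**Figure D3:**
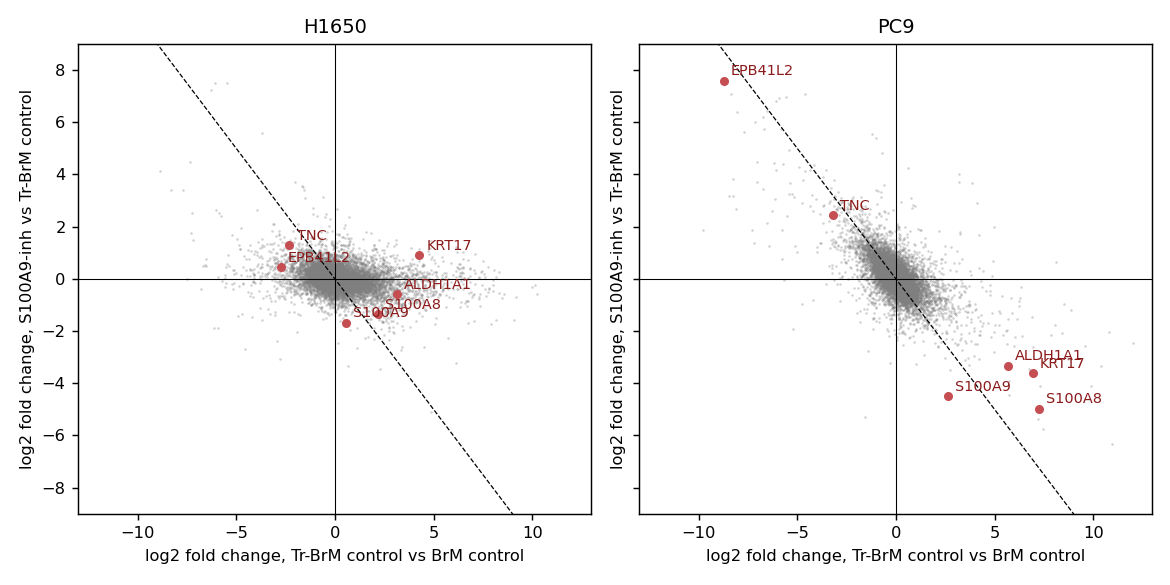
Log2 fold change of every tested gene in Tr-BrM against BrM controls (x axis) and in S100A9-inh against Tr-BrM controls (y axis) in H1650 and PC9, with 6 named genes in red and a dashed line where the second change would undo the first. The correlation across genes is -0.285 in H1650 and -0.67 in PC9, and EPB41L2 in PC9 sits at -8.72 and 7.59.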

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

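The tests of RNA from other cells, of a cell mixture and of shared controls were chosen after the results were seen, as were the list counts between lines with an estimated correlation or another scaling or in splits of the libraries, and the share moved back over all called genes, while the other splits of samples and the test of chromosome regions were set beforehand.

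The effects of Tr-BrM and of S100A9-inh differed between H1650 and PC9 in the interaction test, for 10422 and 7704 genes, and 14 and 15 gene lists passed the threshold. Each real count of genes was the only 1 of 50 splits of the libraries within the lines to reach its size (highest other 4890 and 5141). Splits that mix the groups also remove each line's own change, so they do not show what equal effects in both lines would give. They therefore cannot exclude chance for the gene counts. For lists, 2 of 50 splits reached 14 (highest other 15), a share under 0.05 although another split gave more lists, and 4 of 50 reached 15 (highest other 17). Chance is therefore left open for the list count of Tr-BrM against BrM and not excluded for that of S100A9-inh. With an estimated correlation 6 lists remained past the threshold in each comparison. For Tr-BrM against BrM, the PC9 minus H1650 differences on the log2 scale were 2.05 for S100A9, 5.05 for S100A8, 2.52 for ALDH1A1, 2.27 for ALDH1A3, 0.88 for EGFR, 2.60 for GGT6, 2.67 for KRT17, -4.66 for PIP5K1B, -2.89 for CDYL2, -6.91 for TSHZ3, -5.98 for EPB41L2, -0.90 for TNC, -6.58 for FN1, 8.64 for MSLN, 6.18 for CD44, 4.05 for MSN and -6.18 for LIPG. Those of PIP5K1B, TSHZ3 and GGT6 rest on groups with 0 to 3 counts. The call for GGT6 was lost without H1650 BrM control replicate 1 (2.05), PC9 BrM control replicate 2 (2.15) or PC9 BrM control replicate 3 (2.12). Its value ran from 2.05 to 4.61 over all alternatives. For S100A9-inh they were -2.81 for S100A9, -3.62 for S100A8, -2.73 for ALDH1A1, -1.21 for ALDH1A3, -0.59 for EGFR, 1.16 for TNC, 0.47 for LOXL2, 0.71 for AXL, -0.28 for GLDC, -0.54 for KRT13, -1.10 for SPP1, -1.21 for WNT6, -4.52 for KRT17, 7.16 for EPB41L2, 4.09 for BST2, -1.96 for THBS1 and -2.41 for KLK5. The call for GLDC was lost without H1650 Tr-BrM control replicate 2 (-0.28), H1650 S100A9-inh replicate 3 (-0.24), PC9 Tr-BrM control replicate 1 (-0.25) or PC9 S100A9-inh replicates 1 (-0.28) or 2 (-0.29). That for KRT13 was lost without H1650 Tr-BrM control replicates 1 (-0.53) or 3 (-0.52), H1650 S100A9-inh replicates 2 (-0.52) or 3 (-0.56), PC9 Tr-BrM control replicates 1 (-0.48) or 3 (-0.56) or PC9 S100A9-inh replicate 2 (-0.34).

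Within each line, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each comparison the real split, 1 of 10, had the highest count. Every other split mixes the groups and so adds their difference to the spread within groups. Low gene counts in those splits could thus be foreseen, and they cannot decide on chance. In H1650 the real counts were 11469 (highest other 0) for Tr-BrM against BrM, 5230 (2) for S100A9-inh against Tr-BrM and 11416 (0) against BrM, and for lists 14 (12) and 16 (11). In PC9 they were 9684, 8487 and 7489 (0 in each), and for lists 8 (6) and 15 (7).

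Astrocyte and myeloid markers were higher in H1650 Tr-BrM than in BrM. RNA from other cells is a candidate source: the median rise was 0.939 CPM over 12 abundant myeloid transcripts, 6 of which at least doubled, and 4.09 CPM over 15 abundant astrocyte transcripts, 13 of which at least doubled. LYZ among the 12, and AQP4, SPARCL1 and SLC1A2 among the 15, are themselves list markers that rose, so they are no separate support. Lower in Tr-BrM were SRGN (178 to 36.7 CPM) and CD14 (3.21 to 2.44) of the 12, and CPE (46.6 to 13.6) of the 15. At 1 CPM or more, BrM cells already held 7 of the 12 and 11 of the 15. An earlier bound, on the rise of the list markers (4.48 CPM) and of GFAP (54.5 CPM), counted against both sources and was set aside after its values were seen, because it assumed an expression profile, so both sources stay open. For a single source that changed by 1 factor under S100A9-inh, the scatter of the markers' changes was measured. Cochran's Q per degree of freedom was 5.8 for 10 myeloid and 21.2 for 8 astrocyte markers (15.6 pooled, tested first and split by list afterwards). These changes include each marker's level in BrM. Of the list markers that rose, 7 of 14 myeloid and 5 of 10 astrocyte ones were at 1 CPM or more there. Unequal BrM levels would scatter the changes under 1 factor too, and SEs at low counts may be too small. Q therefore cannot decide on a single source. SLC1A3, GJA1 and GJB6, which tumour cells may express themselves, weigh heavily in the astrocyte value, and expression by the tumour cells was not tested.

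In PC9, genes that differed between Tr-BrM and BrM moved back toward BrM under S100A9-inh by a median of 53.5% (quartiles 24.4 and 76.8%) over 897 of the 9684 called genes, those with an absolute log2 fold change of at least 1 and 5 CPM in some group, against 7.6% (quartiles -4 and 25.8%) over 1690 of 11469 in H1650. The fractions were taken on group mean CPM and not on the log2 scale, on which they can differ. The PC9 median was 61.3% over 383 genes higher in Tr-BrM and 45.5% over 514 lower ones. S100A9 itself went from 745 to 33.2 CPM in PC9 and from 307 to 96.2 CPM in H1650. A difference between the lines in response cannot be told apart from this unequal reduction. Over all called genes the medians were 58.2% (quartiles 20.1 and 94.3%) and 11.5% (-12 and 39.5%), and 16.3 and 36.9% of genes moved away. The Tr-BrM controls enter both parts of these fractions, so their error alone can move small changes back, by an amount not estimated. A mixture of Tr-BrM and BrM cells with no other change would put every gene at 1 fraction. The interquartile range was 6.85 times that of a simulated mixture and 9.9% of the 897 genes moved away, which argues against such a mixture. A mixture together with other changes would also spread the fractions and was not tested. The shared Tr-BrM controls would give a covariance of -0.018, and the observed value was -0.4187. An effect of S100A9 inhibition, which the design names, remains a hypothesis, and selection of a subset of cells was not tested.

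A majority of the tested genes differed between Tr-BrM and BrM in each line. Gains and losses of chromosome regions were a candidate explanation. Windows of 50 neighbouring genes explained 7.3% of the variance beyond shuffled order in H1650 and 8.4% in PC9, so most of it did not follow position. A simulated regional shift gave 54.8 and 52.2%, but that share depends on the size of the shift put in. Of called genes, 87.3 and 83.7% still differed from their window's median. A called gene can do so merely because it was called, where its window's median is small. These 2 comparisons therefore cannot count against gains or losses in some regions, which stay open. Differences in culture or handling between the groups stay open, since the labels give no batch and such a difference cannot be separated from the groups.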

How the results depend on the processing

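The list counts between lines with an estimated correlation or another scaling (RLE), the overlaps with DESeq2 on the genes edgeR tested, the split by direction of overlaps at the fold threshold and the recovery by level were chosen after the results were seen, and all other alternatives were planned. Counts of called genes stayed within 1.5 times of the value reported under every scaling, filter, DESeq2, robust empirical Bayes, smaller sample sets and left-out replicates, and moved further only with an absolute log2 fold change of at least 1. That threshold left, in H1650, 3690 genes for Tr-BrM against BrM, 366 for S100A9-inh against Tr-BrM and 3505 against BrM, and in PC9 2053, 1263 and 1197. The reversal then held 199 genes in H1650 and 754 in PC9, and the overlap between lines 339 and 25, because fewer genes pass. Lists past the threshold fell to 0 and 0 in H1650, 2 and 2 in PC9 and 6 and 6 between lines with an estimated correlation, and numbered 39, 26, 37 and 38 with fry, which tests no contrast with other genes. Leaving out 1 replicate gave 10786 to 11220, 4336 to 5317 and 10639 to 11260 genes in H1650, and 9053 to 9270, 7676 to 8397 and 6607 to 7677 in PC9. Interactions gave 10051 to 10206 and 7258 to 7572, reversals 2425 to 2905 and 5303 to 5975, and lists 14 to 17 and 15 to 17 in H1650 and 8 to 13 and 14 to 18 in PC9, with 13 without BrM control replicate 2. No named gene reversed. Of 4659 values of 309 results of genes the text names under alternatives, 65 fell below the fold threshold, 25 lost and 7 gained the call otherwise, over 9 results. The PC9 minus H1650 difference of KRT13 under S100A9-inh was lost in 9 alternatives (adjusted p from 0.024 to 0.24 over all), 7 of which leave out 1 library, and that of GLDC in 7 (0.00761 to 0.112), 5 of which leave out 1 library. That of GGT6 for Tr-BrM was also lost with DESeq2 (adjusted p = 0.0511, range 0.00909 to 0.115). Differences of SRGN, IL11 and WNT5B between lines did not pass and gained the call in 4, 1 and 2 alternatives. The cause was not tested. No paired analysis was possible because the labels share no replicate numbers. Depth limits genes with few counts: of simulated 1.5-fold changes within lines, 27.6% were recovered at 1 to 5 CPM and 95.6% at 5 CPM or more.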
